A study of Drosophila melanogaster with 8 samples.

How the data were processed

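RNA from Dh44 neurons of the adult fly brain was profiled in 8 libraries, numbered 1 to 8 as in the sample titles. Dh44 is the gene of diuretic hormone 44, a neuropeptide related to vertebrate corticotropin-releasing factor. Per the labels' protocols, the flies carried a membrane-bound green fluorescent protein under the control of a Dh44 driver line (the GAL4/UAS system) and were kept on normal food until 5 days. Brains were dissected and fluorescent cells were drawn into a glass micropipette. The series text speaks of individual cells, whereas the treatment label speaks of single cells being pooled in situ, so how many cells stand behind each library is not settled here. Complementary DNA was made and amplified with a SMART-type full-length protocol, sheared to about 250 bp, ligated to adaptors and amplified by 12 cycles of PCR.

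The authors deposited one FPKM value per gene and library, a fragment measure normalised for exon length and for the mapped fragments of the library. Per the labels' protocols and the series text, low-quality reads, adaptors and amplification primers were removed and the reads were mapped to the Drosophila genome. Per the submitters' processing notes, TopHat was among the tools used. Its version, the genome build, the gene annotation, the program that computed FPKM and whether strand was used are not given in the sources used here. FPKM divides by gene length and by the library's mapped fragments, so a value depends on what else is in the library. Short RNAs close to or below the fragment length can receive extreme values.

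Each library held 11773 gene identifiers, of which 11646 were matched to a symbol through the supplied gene name table. The 127 unmatched identifiers carried a median of 2.86% of the summed FPKM and are printed as identifiers. Of 13986 protein-coding genes in the Ensembl release 115 annotation (assembly BDGP6.54), 11297 had a value; the remaining ones, some of them on the gene lists, were not analysed here. No mitochondrial genes were analysed, so the planned rescaling without mitochondrial and ribosomal protein genes left out ribosomal protein genes only. Coordinates, exon lengths and overlaps were taken from BDGP6.54, which may differ from the build used to make the values. Reads from an antisense partner cannot be told apart without strand, and reads in exons shared on the same strand could be split either way. Among the genes chosen by rule and printed with a value, exons overlap an antisense gene for CG13248, JhI-21, CG13384, gb, CG13795, Gr43a, Phm, svr, Yp1, Lsp2, Lcch3, Ddc, Vmat, crq, Hsp83, HisCl1, loco and tim. They overlap a gene on the same strand for CG13743, crc, VAChT, Sxl, srp, tim, Act57B and snoRNA:Or-CD9a. The values of all these genes are uncertain to that extent.

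Read depth is unknown. The values above 0 reached down to 9.13e-317 FPKM, and 105 of them lay below 1e-10, so they are model estimates from which whole reads were not recovered. No counting interval and no detection floor is therefore given. Tbp, a general transcription factor that every cell uses, was at 0 in 5 libraries, so an exact 0 is written as "listed at 0" and is not read as absence.

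All 8 libraries belong to a single group and no animal is named for any of them. Cells are not replicates, so no p-value, standard error or test between groups was computed. Results are FPKM values per library with the median and the range over n = 8 libraries, and every spread is that between libraries. A gene was counted as detected in a library at 1 FPKM or more, and as detected overall when this held in at least 4 libraries. Logarithms are log2(FPKM + 1), with a pseudocount of 1, which compresses differences among low values. Agreement between libraries was the Pearson correlation across 8235 genes listed above 0 in at least 1 library, for each of the 28 pairs.

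Gene lists were fixed before the data were examined. They cover neuronal genes, peptide secretion, neuropeptides, fast and amine transmitters, insulin cells, glia, photoreceptors, fat body, hemocytes, muscle, amino acid transporters, TOR and GCN2 nutrient sensing, sugar sensing, chemosensory receptors, ion channels, receptors for peptides, amines and fast transmitters, clock genes, immediate early and stress genes, housekeeping genes and sex genes. The level of a list was its median of mean log2(FPKM + 1), given as a percentile among 10000 random lists of the same size drawn from all genes. Variability was the SD of log2(FPKM + 1) over libraries minus the running median over 201 genes of similar mean. For lists, this was set against 10000 random lists matched on mean level in 20 bins. Only genes with a mean log2(FPKM + 1) of 3 or more were ranked by variability.

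The genes named were set by a rule written before the data were examined: Dh44; CG13248, mnd, JhI-21, slif and path; up to 15 detected amino acid transporters by median; up to 5 detected members of each other list by median, with the highest single value in the lists of other cell types; the 15 genes of highest median apart from ribosomal protein genes; and the 10 most variable genes. Other genes are also named, only some of them from lists with few detected members, and were chosen after their values were seen.

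Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots used Matplotlib 3.10.9. Both gene-wide steps were tested on simulated or redrawn data. Among 3152 genes, ranking by variability recovered 65.5% of 200 genes given an added SD of 3 on the log2 scale and 17.5% of 200 given an added SD of 1. The simulated values had normal noise with the running median as SD and no exact zeros. Many measured genes were listed at 0 in some libraries, so these shares may not carry over. Of 1000 random lists of 20 genes, 4.8% lay above the 95th percentile. Such a share follows from drawing both kinds of list from the same values, so it checks the computation only. A list of 20 genes raised by 3 on the log2 scale reached percentile 99.6. The alternatives tried were other detection thresholds and numbers of libraries, a pseudocount of 0.1, rescaling of each library, filters on low genes, Spearman correlation and the omission of each library in turn. Omission of libraries 1 and 8 together and a limit on exon length were added after the data had been seen.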

Results

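The series addressed an internal sensor of dietary amino acids in Drosophila melanogaster, and profiled the neurons that make the peptide Dh44. Expression was measured by RNA sequencing in 8 libraries of Dh44 neurons from the brain of 5-day-old flies, with no second cell type or diet to compare them with. The questions that this design allows are which transporters, sensors, peptides and receptors were detected in these neurons, and how far the libraries differed. Summed FPKM ranged from 812029 to 935440 per library, and read depth is unknown. A median of 4855.5 genes reached 1 FPKM. Library 1 had the fewest at 2518, followed by library 8 with 3798 and library 3 with 4094, and library 4 had the most at 5256. The 10 most abundant genes of a library held 24.4% to 32.4% of its summed FPKM, and ribosomal protein genes held 17.8% to 25.4%.

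Dh44, the gene whose driver line marked the cells, was among the 5 most abundant genes in every library. Its median was 60073 FPKM, with a range from 26309 in library 8 to 99818 in library 2. It ranked first in libraries 1 and 7, second in 5 libraries and at rank 5 in library 8, and held between 2.81% and 11.1% of a library's summed FPKM. The gene (FBgn0012344) lies on chromosome 3R from 9638182 to 9650706 on the plus strand. The highest median of all belonged to lncRNA:noe, a noncoding RNA, at 79874 FPKM with a range of 6056 in library 8 to 114469 in library 4.

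Among amino acid transporters, CG13248 stood apart. CG13248 is a predicted cationic amino acid transporter, chosen before the data were examined because it was known from the study of these neurons. Its rank here is therefore not independent of that earlier knowledge. It had a median of 832 FPKM and was the highest of the 41 transporters measured in 7 of 8 libraries. In those 7 libraries it lay between 711 and 1010 FPKM, and it was 2.49 to 12.7 times as high as the next transporter. In library 8 it was 84.7 FPKM, the fifth highest transporter after path at 209 FPKM. Its median was 5.61 times that of the second transporter, CG13743 (148 FPKM), and ranked 153 among all genes. The exons of CG13743 overlap CG8197 on the same strand, so its value and this ratio are uncertain. CG13248 (FBgn0036984) lies on chromosome 3L from 20407103 to 20410566 on the minus strand, and its exons overlap the antisense noncoding gene lncRNA:CR45973, whose reads cannot be separated without strand.

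The comparators fixed with CG13248 were lower. The median of path, a proton-assisted amino acid transporter with a role in growth, was 125 FPKM (39.8 to 285). JhI-21 and mnd, light chains of heterodimeric transporters, had medians of 26.3 and 13.4 FPKM, and each was listed at 0 in 2 libraries. The exons of JhI-21 overlap the antisense gene PLCXD. slif, a cationic amino acid transporter that acts in nutrient sensing in the fat body, was listed at 0 in 5 libraries and reached 12.7 FPKM in library 5. The lowest value of CG13248, in library 8, lay within the range of path, so the separation between these genes does not extend to that library.

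In all, 20 of the 41 transporters reached 1 FPKM in at least 4 libraries, and 5 did so in all 8. These 5 were CG13248, CG13743, path, CD98hc (median 79.5 FPKM), which is the heavy chain partner of the light chains, and the glutamate transporter Eaat1 (16.5 FPKM). A further 16 reached 1 FPKM in 1 to 3 libraries and 5 in none. Between these extremes were sbm (39.6 FPKM), CG13384 (29.2), CG12531 (27.7), Eaat2 (25.0) and CG30394 (10.1), given as median FPKM. Lower medians were those of gb (3.99 FPKM), CG10804 (3.40 FPKM) and CG13795 (3.31 FPKM). CG13795 was unevenly distributed, at 156 FPKM in library 8 and 79.7 FPKM in library 1. The count of 20 depended on the threshold: 13 transporters were detected at 5 FPKM and 26 at 0.1 FPKM. When detection was required in at least 2 libraries there were 30, and in at least 6 libraries 11. The list as a whole lay at percentile 74.6 of random gene lists, and at percentile 11.7 when genes listed at 0 everywhere were left out of the list and of the pool.

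**Figure D1:**
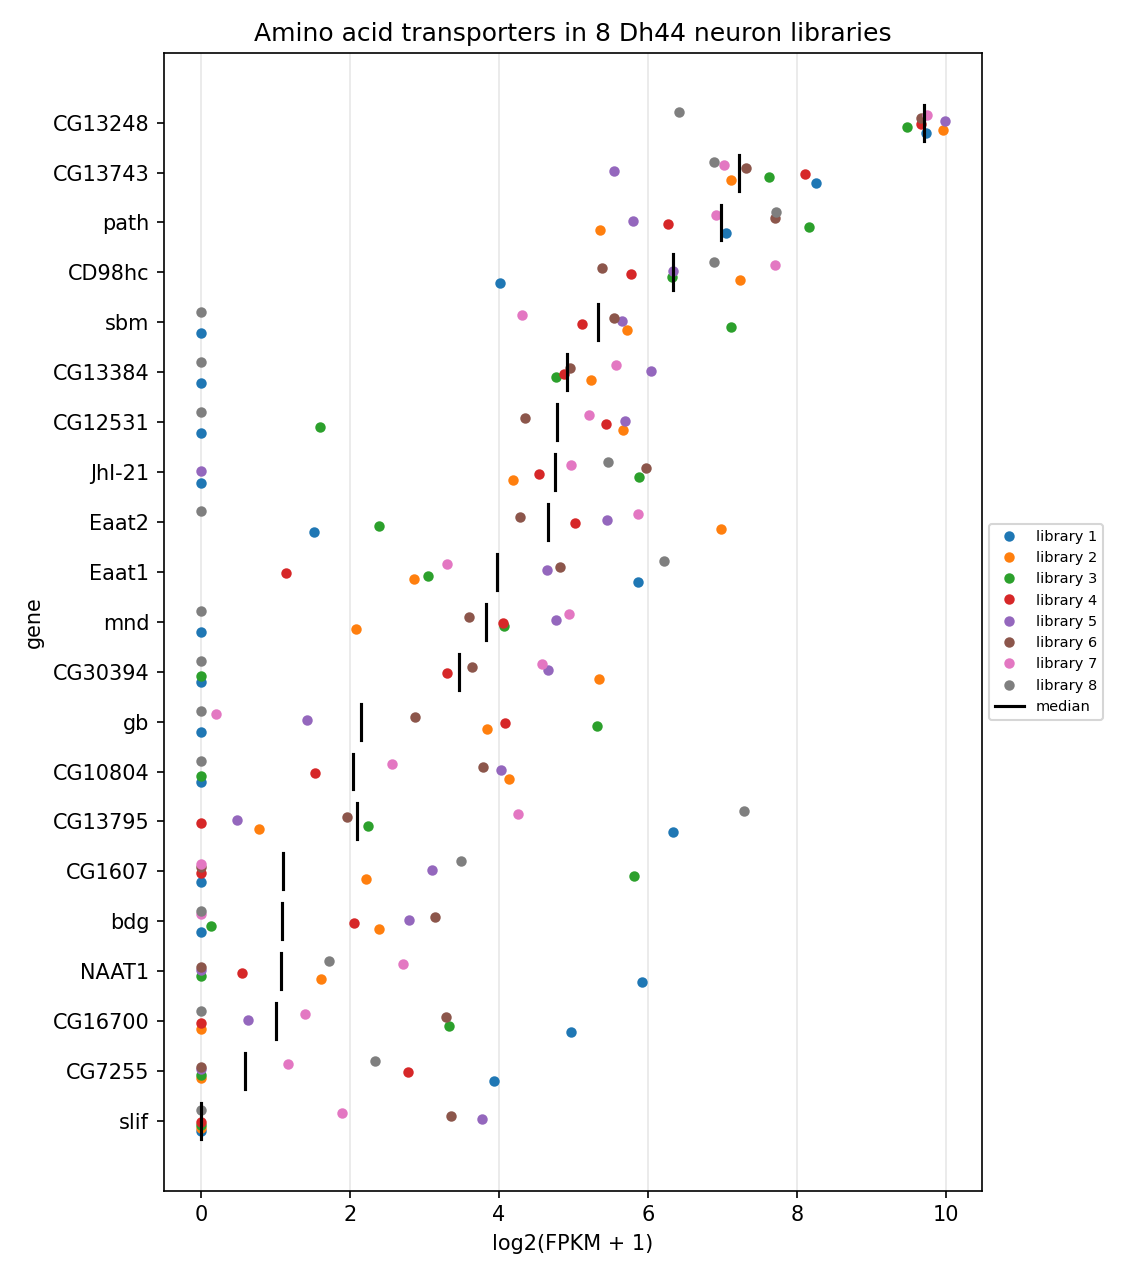
FPKM of the 20 detected amino acid transporters and slif, as log2(FPKM + 1) on the horizontal axis, with 1 point per library and a black bar at the median of the log2 values over 8 libraries. CG13248 lies between 711 and 1010 FPKM in 7 libraries and at 84.7 FPKM in library 8, whereas slif lies at 0 in 5 libraries.

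Genes of intracellular nutrient sensing were detected in part. In the TOR and GCN2 list, 10 of 13 measured genes were detected in at least 4 libraries. The highest was crc, the fly ATF4 factor of the amino acid response, at a median of 371 FPKM (255 to 597). It was followed by Thor, the translational repressor 4E-BP, at 80.7 FPKM (4.81 to 566) and the kinase S6k at 36.7 FPKM (17.9 to 83.3). Rheb, an activator of TOR, had a median of 29.6 FPKM and foxo 13.7 FPKM. Gcn2, the kinase that responds to uncharged transfer RNA, reached 1 FPKM in 3 libraries. Tor itself was not analysed here. The exons of crc overlap CG46314 on the same strand, so its value is uncertain.

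Of the sugar sensing list, 9 of 24 measured genes were detected. Gr43a, the fructose receptor known from brain neurons, had a median of 79.8 FPKM, reached 1 FPKM in 7 libraries and was listed at 0 in library 1. Its exons overlap those of Dhx15 on the opposite strand, and their reads cannot be separated without strand. The glycolytic enzyme PyK had a median of 241 FPKM. The trehalose transporter Tret1-1 was at 60.7 FPKM, the hexokinases Hex-C and Hex-A at 51.8 and 43.4 FPKM. Among 19 chemosensory receptors measured, only Gr28b was detected in at least 4 libraries, with a median of 13.3 FPKM and values of 1 FPKM or more in 5 libraries. The sugar list lay at percentile 7.53 of random lists, which became 42.3 without genes listed at 0 everywhere.

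The cells had high levels of genes of peptidergic neurons. All 15 neuronal genes measured and all 12 peptide secretion genes measured were detected in at least 4 libraries, 13 and 7 of them in all 8. The neuronal gene elav was at 1.11, 1.40 and 0.82 FPKM in libraries 1, 3 and 8. In libraries 1 and 8 the peptide secretion gene dimm was listed at 0. Both lists lay at percentile 100 of random lists. On this measure the lists of other cell types lay at percentile 99.99 (insulin cells), 99.97 (fat body), 96.5 (photoreceptors), 87.3 (hemocytes), 57.95 (muscle) and 48.2 (glia). Without genes listed at 0 everywhere, photoreceptors lay at 77.6, hemocytes at 65.1, muscle at 11.1 and glia at 5.04. The leading neuronal genes by median were the RNA-binding protein gene fne (475 FPKM), Appl (293), the vesicle proteins Rab3 (287) and Syt1 (226), and Snap25 (186). Peptide secretion was led by 7B2, a partner of the prohormone convertase encoded by amon, at 6498 FPKM. It was followed by the carboxypeptidase gene svr (1548 FPKM), the amidating enzyme gene Phm (1040), amon (978) and Syt4 (407). The exons of Phm overlap those of Sox14 on the opposite strand. In library 8 the median deviation from the other 7 libraries was -1.95 on the log2 scale for the neuronal list and -2.05 for the peptide secretion list. In library 1 these deviations were -0.64 and -1.32.

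Besides Dh44, several other peptide genes were abundant. In the neuropeptide list, 12 of 24 measured genes were detected. Gpb5, a glycoprotein hormone subunit, had a median of 3494 FPKM (699 to 5333), so Dh44 was 17.2 times as high by the ratio of medians. The insulin-like peptides Ilp2 and Ilp3, made by neighbouring median neurosecretory cells, had medians of 2724 and 543 FPKM and exceeded 1 FPKM in all 8 libraries. Ilp5 ranged from 2.95 FPKM in library 5 to 15384 FPKM in library 3, around a median of 161. Library 3 also had the highest Ilp2 (7261 FPKM) and Ilp3 (10275 FPKM). Nplp3 was at 282 FPKM (146 to 496). The other detected peptides were Nplp1, Akh, Pdf, sNPF, amn and Ilp6. The fat body list also holds Ilp6, which was highest in library 8 at 160 FPKM. Many neuropeptide genes were not analysed here.

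**Figure D2:**
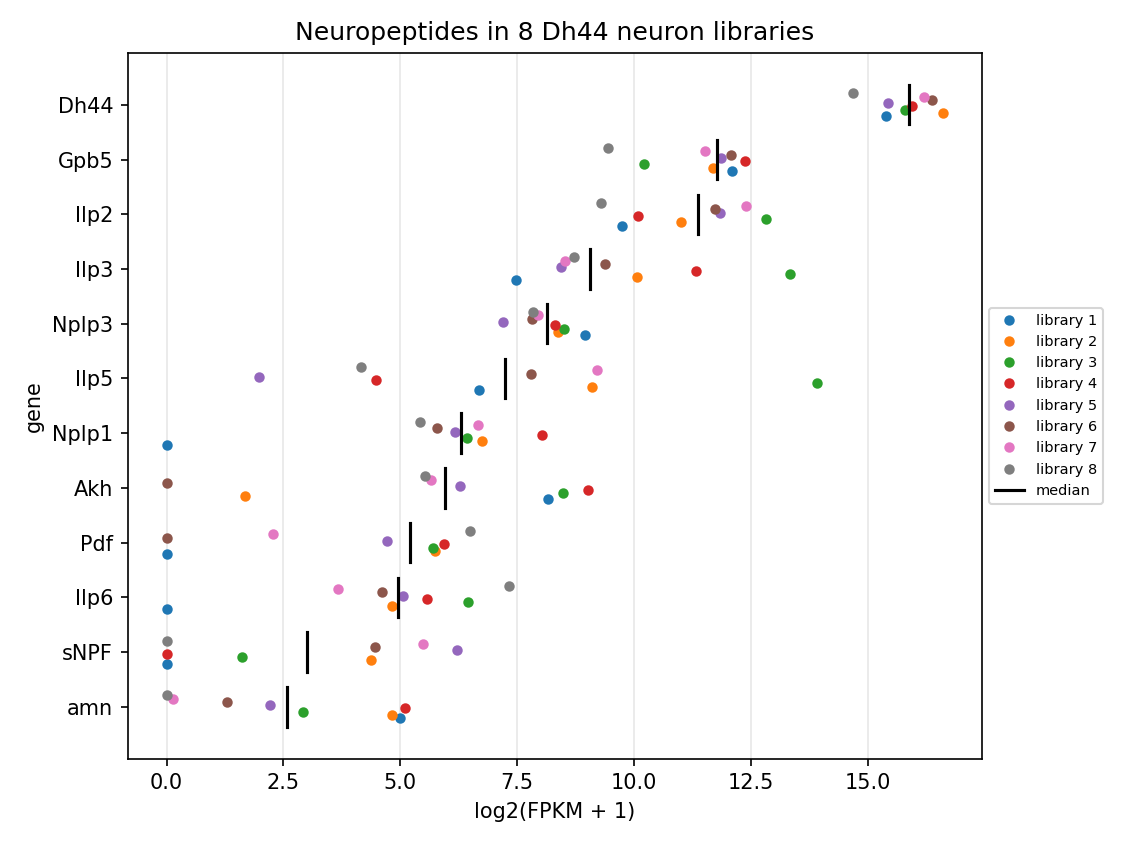
FPKM of the 12 detected neuropeptide genes, as log2(FPKM + 1) on the horizontal axis, with 1 point per library and a black bar at the median of the log2 values over 8 libraries. Dh44 is above every other peptide in each library, and Ilp5 spreads from 2.95 to 15384 FPKM.

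Receptors and channels were detected at lower levels. Across the peptide receptor, amine receptor, transmitter receptor and ion channel lists, 37 genes were detected in at least 4 libraries. Ion channels made up 19 of 27 measured, led by the potassium channel gene Sh (113 FPKM), its regulator qvr (72.9) and the calcium channel gene cac (40.5). Of 9 transmitter receptors, 6 were detected, led by GluClalpha (57.8 FPKM), Lcch3 (29.7) and GABA-B-R2 (27.8). Of 12 amine receptors, 7 were detected, led by Octalpha2R (26.2 FPKM), DopEcR (10.4) and 5-HT7 (6.68). Of 11 peptide receptors, 5 were detected, led by CCKLR-17D3 (33.4 FPKM), and Dh44-R1 had a median of 14.1 FPKM with 4 libraries listed at 0. In library 1 the median deviation was -3.01 on the log2 scale for ion channels and -4.37 for transmitter receptors.

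Transmitter genes gave few clear values. The serotonin transporter gene SerT was at or above 1 FPKM in all 8 libraries, with a median of 147 FPKM (29.0 to 292). Of 10 amine transmitter genes measured, 4 were detected, namely SerT, Ddc (21.1 FPKM), ple (2.59) and Vmat (2.16). Of 4 fast transmitter genes measured, 2 were detected, VGAT at 12.5 FPKM and VAChT at 2.90 FPKM. VAChT shares exons with ChAT, so its value is uncertain.

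Genes known from other cell types were present in the same libraries. The yolk protein genes Yp1, Yp3 and Yp2, expressed in fat body and ovary, had medians of 10814, 8005 and 4879 FPKM, and the storage protein gene Lsp2 958 FPKM. In the fat body list 7 of 11 measured genes were detected, and the list held 1.55% to 7.35% of summed FPKM per library. Libraries 8 and 1 had the largest fat body shares (7.35% and 7.02%) and, of the 8 libraries, the lowest medians of neuronal genes relative to the others. Of 15 photoreceptor genes 13 were detected, led by the opsin gene ninaE (925 FPKM) and the arrestin genes Arr2 (399) and Arr1 (214). Rh5, another opsin, was at 3995 FPKM in library 8 with a median of 0. Of 11 glial genes 5 were detected, led by Gs2 (56.7 FPKM) and nrv2 (40.2), while the glial factor repo had a median of 0.378 FPKM. Of 6 hemocyte genes 4 were detected, led by crq (66.6 FPKM), and of 11 muscle genes 3, led by Mlc2 (22.4 FPKM). Of the 4 insulin cell genes, Ilp2, Ilp3 and Ilp5 were detected in all 8 libraries and Dsk reached 1 FPKM in 2.

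**Figure D3:**
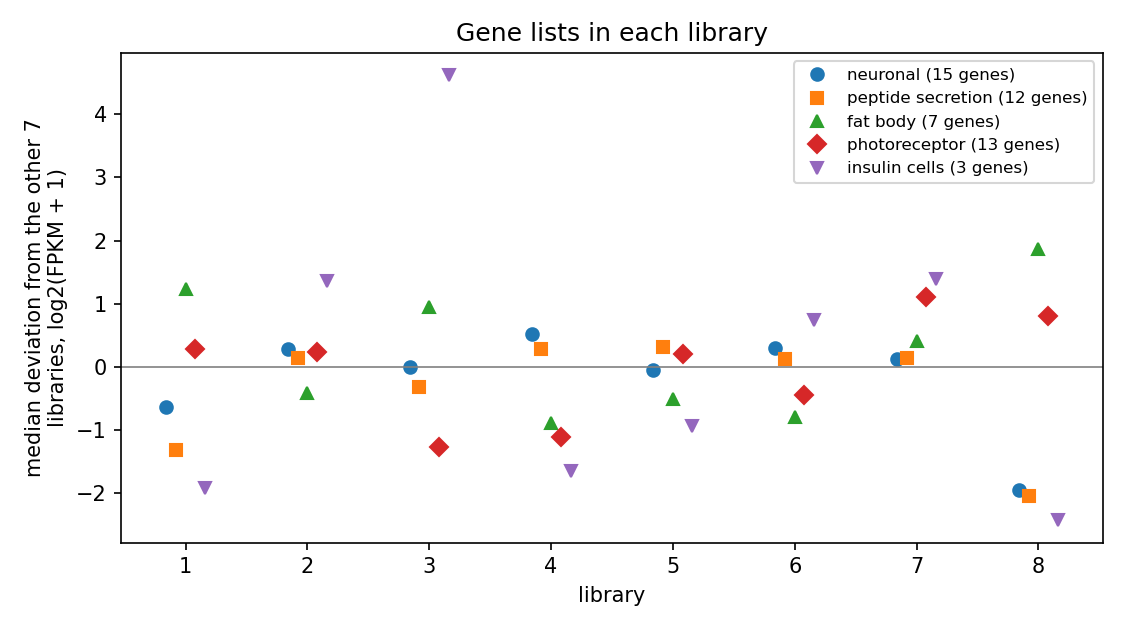
Median deviation of 5 gene lists in each library from the median of the other 7 libraries, in log2(FPKM + 1) on the vertical axis, with libraries 1 to 8 on the horizontal axis and 1 symbol per list. In library 8 the neuronal list lies at -1.95 and the fat body list at 1.86, and in library 3 the insulin cell list lies at 4.62.

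Agreement between libraries was moderate. Across genes, the Pearson correlation of log2(FPKM + 1) had a median of 0.620 over the 28 pairs (0.513 to 0.733), and the Spearman correlation a median of 0.547. Genes are not independent replicates, so these values describe similarity only. Libraries 1 and 8 had the lowest medians against the others, 0.531 and 0.542. The gene list that varied least for its level was the neuronal list, at percentile 0.04 of matched random lists. The insulin cell and neuropeptide lists varied most, at percentiles 99.4 and 98.8. All 10 most variable genes were small nucleolar or other small noncoding RNAs with exons under 250 bp, among them snoRNA:Me28S-A1322 (SD 5.73) and snoRNA:Or-CD11c (SD 5.58), with SD in log2 units over 8 libraries. Among genes with exons of 250 bp or more, none of these 10 is left and the leading genes were Rdh, Ilp5 and CG34242, named after their values were seen.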

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

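All tests in this part, and their bounds, were chosen after the results were seen, apart from the comparison of each library with the others. For 130 items (127 named genes and 3 measures of the libraries), the highest and the lowest library were compared with the rest, and 35 stood out by a gap, relative to the range of the 8 libraries, above Dixon's 95% critical value. Chance gives about 1 in 20 under a normal distribution, but this is no yardstick here: FPKM is skewed towards high values, and some genes, such as Rh5 and the small nucleolar RNAs, were named because of a high single value or a large spread. Of the 35, 16 were in library 8, 7 each in libraries 1 and 3, 3 in library 2, and 1 each in libraries 4 and 7.

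CG13248 was lowest in library 8 at 84.7 FPKM, against a median of 851 in the other 7 libraries. Neuronal and peptide secretion genes were also lower there: 24 of 27 fell below their medians in the other libraries, and the median deviation of these 27 genes was -1.95 on the log2 scale. CG13248 deviated by -3.31, at percentile 18.5 of those 27 genes. Against the 20 of them at 1 FPKM or more in all 8 libraries, whose median deviation was -1.73, it lay at percentile 10. Dh44, the marker of the picked cells, deviated by -1.27. Housekeeping genes had a median deviation of -0.90 with 9 of 11 lower, so the fall was not confined to neuronal genes. A lower share of neuronal RNA in library 8 may account for part of the low value. CG13248 fell further than Dh44, 7B2 (-1.86) and Gpb5 (-2.40), whereas Phm fell slightly further still (-3.41). In library 1, where the peptide secretion list deviated by -1.32, CG13248 deviated by 0.07. Lists of other cell types had median deviations of 1.86 (fat body, SD 0.89 over genes), 1.70 (glia, SD 2.93), 0.81 (photoreceptor, SD 2.87), -0.03 (hemocyte, SD 1.93), -0.17 (muscle, SD 2.98) and -2.43 (insulin cells, themselves neurons, SD 1.49), so they did not all rise. The design names no group that separates library 8, so no biological explanation was tested and a real difference of its cell material in CG13248 stays open.

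Library 8 was also highest for secreted peptides of the immune response, Dso2 at 39937 FPKM and BomS6 at 24040 FPKM. Their exons of 223 and 198 bp lie below the fragment length of 250 bp, where FPKM can be extreme. This length is the same in every library, so by itself it does not account for library 8 being highest. BomS6 was next highest in libraries 1 (10114 FPKM) and 3 (10046 FPKM), as was Yp1 (21961 and 19523 FPKM). Dso2 was next highest in libraries 1 (14413 FPKM) and 2 (12655 FPKM). A shared source was not tested. CG6503 (exons of 408 bp) at 32104 FPKM and FBgn0040813 at 24705 FPKM were highest in library 8 too. These genes were abundant elsewhere too, with medians in the other 7 libraries of 9831 (Dso2), 6105 (BomS6), 6831 (CG6503) and 6769 FPKM (FBgn0040813). Of the photoreceptor genes, ninaE (2543 FPKM), Arr2 (891 FPKM) and Rh5 (3995 FPKM) stood out in library 8, whereas 6 of 13 detected genes of that list were lower there than in the other libraries. Of 8 clock genes, 3 stood out there, cwo at 100.4 FPKM, vri at 92.7 FPKM and tim at 50.9 FPKM. Pdp1 (116.8 FPKM) and Clk (27.1 FPKM) were also highest there. The 6 detected clock genes had a median deviation of 2.36 in library 8 (SD 2.60 over genes), and 1 of them was lower. In that library cry was at 5.94 FPKM, below its 40.5 FPKM in library 2, and cyc was listed at 0. There per was listed at 0 too, as in 6 libraries in all. Further values of library 8 were 336 FPKM for Tret1-1, 45.5 FPKM for srp, 39.9 FPKM for ple, 15875 FPKM for snoRNA:Or-CD11c and 10802 FPKM for snoRNA:Or-CD9a.

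Ilp2, Ilp3 and Ilp5 were at 1 FPKM or more in every library, whereas Ilp1 and Ilp7 were listed at 0 in all 8, and in library 3 Ilp3 (10275 FPKM) and Ilp5 (15384 FPKM) lay far above the rest. A single pool of insulin cell RNA in every library would keep Ilp2, Ilp3 and Ilp5 in a fixed ratio. The median SD of their log2 ratios was 3.04, against 1.24 for random sets of genes also at 1 FPKM or more in all 8 libraries and of like level, which is percentile 98.6 (92.7 to 98.6 without each library in turn), and the ratio of Ilp5 to Ilp2 ran from 0.000806 in library 5 to 2.12 in library 3. Ilp5 alone had an SD of 3.73 on the log2 scale, against 1.29 for Ilp2 and 1.89 for Ilp3, and enters most of these ratios. The random sets were matched on level but not on spread. The percentile therefore largely restates the spread of Ilp5, seen before the test, and is not separate evidence. The swing of Ilp5 against Ilp2 still argues against a single pool of fixed makeup as the whole source of both. The bound at the 50th percentile, earlier at the 95th, and the choice of random genes were both changed after values had been seen. The first form of the test had left the pool open. RNA from insulin cells of differing makeup and expression in the picked neurons themselves stay open and were not tested.

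Library 3 was also highest for sbm (138 FPKM), gb (39.0 FPKM), HisCl1 (53.0 FPKM) and the muscle genes wupA (60.8 FPKM) and Act57B (49.1 FPKM). Library 1 was highest for PyK (580 FPKM), Lsp1beta (186 FPKM), Rheb (155 FPKM), Hml (74.6 FPKM), loco (33.9 FPKM), CG6126 (81.6 FPKM) and Octbeta3R (14.5 FPKM). Library 2 was highest for Hex-A (149.6 FPKM), Eaat2 (126 FPKM) and snoRNA:Me28S-G764 (7477 FPKM). GABA-B-R1 stood out in library 4 at 42.4 FPKM and Hsp26 in library 7 at 609 FPKM.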

How the results depend on the processing

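Of 114 recomputed values of the main results, 108 stayed within the spread (SD) between libraries or, for counts, within 1.5 times. This bound is loose, so the number is no measure of robustness. The spread was near the median itself for mnd (11.4 against 13.4 FPKM) and JhI-21 (23.9 against 26.3 FPKM). Omission of a single library can also move a median only to a neighbouring middle value. The median correlation was 0.515 for genes with a median of 1 FPKM or more (the cause was not tested), and CG13248 had a median of 1162 when libraries were rescaled to a common total without ribosomal protein genes, and 937 when rescaled with them. Detected transporters numbered 13 at 5 FPKM, 11 in at least 6 libraries and 5 in all 8, against 26 at 0.1 FPKM and 30 in at least 2 libraries. With exons of 250 bp or more, a limit added after seeing the data, 0 of the 10 most variable genes were shared. Omission of each library in turn gave medians of 814 to 851 FPKM for CG13248, 11.1 to 15.6 for mnd, 22.2 to 30.3 for JhI-21, 119 to 131 for path and 0 for slif. It gave 17 to 18 transporters, because 4 of 7 libraries were then required, and 8 to 10 shared variable genes. Without libraries 1 and 8, also added later, 15 transporters, 12 neuropeptides, 19 nutrient sensing genes and 37 receptors and channels were detected in at least 4 of the other 6, and 19, 12, 22 and 41 in at least 3; CG13248 had a median of 837 FPKM. Of 69 list percentiles, 15 moved, 14 of them when genes listed at 0 everywhere were left out. That setting took 3538 of 11773 genes out of the random pool, which by construction raised the level of the random lists. List members at 0 everywhere were taken out as well, which raised the lists that held many of them. No paired analysis was possible because there is a single group. Unknown depth limits every value near 0.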

Other observations

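The tests of the fat body pattern in this part, with their gene sets and bounds, were chosen after the results were seen. Of 19 stress and activity genes, 14 were detected. They were led by the small heat shock gene Hsp23 (1327 FPKM, 184 to 2217), the secreted stress peptide gene TotA (670 FPKM), Hsp83 (434 FPKM) and CrebA (118.5 FPKM). Hsp70Aa, Hsp70Ab and Hsp70Ba stayed below 1 FPKM in every library, and Hsp68 and Hsp67Bc reached it in 1 library each. These undetected genes were chosen after their values were seen. TotA was highest in libraries 1 (2864 FPKM) and 8 (2231 FPKM), which also had the largest fat body shares. Activity-regulated Hr38 and sr had medians of 47.6 and 61.2 FPKM and were chosen after their values were seen. The list lay at percentile 100 of random lists, as did the housekeeping list, of which 11 of 12 genes were detected. The libraries hold no cells left unpicked, so no comparison with undisturbed neurons was possible.

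Clock genes were detected for 6 of 8, led by Pdp1 (50.4 FPKM) and cwo (15.2 FPKM), while Clk and per each reached 1 FPKM in 2 libraries. Of the sex genes 4 of 8 were detected: Yp1 and Yp2, which the fat body list also holds, Sxl (54.2 FPKM) and fru (14.5 FPKM). Corazonin (Crz) was at 402 FPKM in library 1 and listed at 0 in the other 7, and was chosen after its values were seen.

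Fat body transcripts were present in every library, with Yp1 between 6630 and 28705 FPKM and Lsp2 between 538 and 5104 FPKM, and RNA carried over from fat body cells would add them in a fixed ratio. Among the 6 fat body genes at 1 FPKM or more in all 8 libraries, the median SD of log2 ratios was 0.53 against 1.15 for random sets under the same rule and of like level, which is percentile 0.98 (0.69 to 2.70 without each library in turn), but Yp1, Yp2, Yp3 and Lsp2 alone, the set used first, lay at percentile 6.18 (4.25 to 10.2). The 6-gene value goes with carry-over, while the 4-gene value misses the bound at the 5th percentile. Pairs without Lsp1beta had SDs of 0.24 (Yp1 to Yp3) to 0.58 (Lsp2 to Lsd-1). With Lsp1beta the SD was 0.83 for Yp1, whose ratio to it ran from 56.7 to 342, and 1.18 for Lsp2. Lsp1beta thus followed the others less closely, and whether 1 source of fixed makeup supplied all 6 genes is not settled. Expression in fixed proportion to the neurons' own transcripts stays open. The SD of ratios to 20 neuronal and peptide secretion genes was 1.58 against 1.29 at random, which is percentile 97.9 (99.5 without library 1). Without library 8 it was at percentile 58.7, near the middle of the random sets, so the high percentile rests on that library. Some earlier forms of this test, with other genes and bounds, had also left it open. Inflated FPKM of short transcripts is argued against by exons of at least 1611 bp, and neither a biological explanation nor whether picking by fluorescence would exclude fat body cells was tested.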
